A study of Homo sapiens with 8 samples.

How the data were processed

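Gene expression was measured by RNA sequencing in 8 libraries from 4 established human cancer cell lines. Each line gave 1 library after 16 h with LAK31 at its own EC50 and 1 after the solvent DMSO. Per the labels' protocols, 300 ng of total RNA per sample went through mRNA capture, fragmentation and a stranded mRNA library kit, and single-end reads of 150 bp were made. The series' design text instead speaks of 3' sequencing, and the sources used here do not settle which description holds. Fold changes of counts hold under either description, but TPM values, which are scaled by transcript length, would be off for a 3' protocol. The EC50 doses are not given in the sources used here, so the lines may have received different doses.

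Per the submitters' processing notes, reads were converted with bcl2fastq and the build was hg38. The overview deposited with the results names CLC Genomics Workbench 20.0.4 and the Ensembl GRCh38 genome for mapping and statistics. The Ensembl release, and whether counting used the strand, are not given in the sources used here. Overlapping genes, genes on opposite strands at 1 locus, readthrough transcripts and close paralogs are therefore uncertain. Of the deposited values, the counts are whole numbers of reads per gene with no scaling, per the file headers, and the totals per library lay between 18734749 and 21887517. TPM values were deposited by the authors beside the counts and are scaled by transcript length and library. A further deposited score, which the file headers call CPM, is each count over an effective library size chosen by the authors, with column sums that differ between libraries, and it was only checked. Per the file headers, the authors also deposited a log2 fold change, a p-value, an FDR and a Bonferroni p-value for LAK31 against DMSO in each line. The header of the 2102EP comparison misspells the line's name, and its fold changes equal the ratio of the 2102EP columns up to a constant. The deposited FDR matched a Benjamini-Hochberg adjustment of the deposited p-values to within 1.6e-05 in all 4 lines.

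The deposited p-values compare 1 library with 1 library, which leaves no replicates from which to estimate spread. Solving for the dispersion behind each p-value, over the 4377 to 5996 genes per line with more than 500 counts in both libraries and a p-value that can be solved, gave 0.00312 at the median and near both ends of the distribution in every line. That is a fixed coefficient of variation of 5.59% for the genes solved, and genes with fewer counts were not checked. A test on the reads of 2 libraries compares those libraries and not the conditions, and the deposited calls are used here in that sense only.

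Genes changed across the lines were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. The test was the quasi-likelihood F test with TMM scaling, the default expression filter on the design, treatment as the term tested and cell line as a block, which left 3 residual degrees of freedom. It is 2-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 over 17874 genes. The labels pair the libraries by cell line, so the block is part of the design. The replicates of this test are cell lines, and its p-values weigh the mean change against the spread between these 4 lines. With 1 library per line and treatment, that spread also holds differences between single libraries. The test moderates the spread of each gene with that of other genes. Log2 fold changes are given with standard errors, and each line's own log2 fold change was computed from TMM-scaled counts with a prior count of 2. Each standard error is the absolute log2 fold change over the square root of the moderated F. It is therefore not the standard error of the 4 lines' own fold changes, and it can be smaller. Folds within a line carry 95% intervals from counting. Where 1 library held 0 counts, the fold was set against a floor of 3 counts in that library and is a lower bound, and 0 counts allow up to 0.16 CPM in the shallowest library. No fold is given where both libraries hold 3 counts or fewer. Intervals and floors cover counting error only.

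Per line, genes past the authors' FDR under 0.05 and an absolute fold change of at least 1.5 were counted, thresholds that stand in the name of the authors' overview. Fixed before the data were examined were the designs, 41 gene lists, the alternatives and the rule for named genes, except where a choice is said to have come later. The rule took, per line, the 5 genes with the largest fold up and the 5 down past these thresholds, with a mean of at least 1 TPM. Across lines it took the 10 up and the 10 down with the largest mean log2 fold change among genes past the thresholds in the same direction in all 4 lines. In each list described it took up to 4 members with the largest mean change, and up to 2 of a line that stands apart. CDKN1A, MYC, HEXIM1 and the identity genes POU5F1, SOX2, KRT5, PAX8 and HOXB13 were always included, and 1 further gene of the rule is not reported here. Clone and accession names were left out. Older symbols were matched for 62 list genes, and symbols are printed as in the deposited file. Coordinates come from the GENCODE release 29 annotation of GRCh38, in which 57835 of 58173 gene identifiers were found.

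Each list was tested across lines with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 41 lists. Members were also adjusted over the list alone. Within a line, the median log2 fold change of a list is given with its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test of the treatment. Some lists share members, such as HEXIM1 and TXNIP in both lists of inhibitor-induced genes, and are not independent.

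On simulated counts with the real means and library sizes, the edgeR test recovered 21% of 2-fold and 64.6% of 4-fold changes over 17420 genes, with 12 false among 97 calls. The list percentile placed 100% of lists raised 2-fold above the 95th percentile and 4.4% of unchanged lists. The alternatives were DESeq2 1.42.0, its size factors inside edgeR, no expression filter, no block, limma on log2(CPM + 1), a threshold of 0.1, leaving out each cell line, other fold and p thresholds for the deposited calls and an estimated list correlation. Added after seeing the data were leaving out mitochondrially encoded genes, removing a trend with GC content, assumed coefficients of variation of 5.59%, 10%, 20% and 40% within a line, and leaving out each line from the list tests. Gene Ontology terms deposited by the authors beside each gene were also tested, after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the remaining work. No interaction between line and treatment was tested, since 1 library per line and treatment leaves no error for it.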

Results

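The response of urological tumour cells to LAK31, which the labels call an epigenetic agent, was followed in 4 lines of different origin. 2102EP is an embryonal carcinoma line, from a germ cell tumour that is not a seminoma, while the carcinoma lines are VM-CUB-1, of the urothelium, Caki-1, of the kidney, and DU-145, of the prostate. Cells were kept for 16 h with LAK31 at the EC50 of their line or with DMSO, the solvent, and RNA was sequenced from 1 library per line and treatment. The 8 libraries held between 18734749 counts, in DU-145 with DMSO, and 21887517, in 2102EP with DMSO. Differences within a line have no replicate check, and only the comparison across the 4 lines is replicated.

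The libraries of 2102EP, VM-CUB-1 and Caki-1 carried the marker genes of their labels, while those of DU-145 lacked the prostate gene examined. In 2102EP, the pluripotency genes LIN28A, POU5F1, DPPA4, NANOG and SOX2 stood at 1585, 1292, 313, 266 and 237 TPM with DMSO, and POU5F1 did not exceed 3.02 TPM in any other library. TPM values assume reads along the whole transcript, which the series' mention of 3' sequencing leaves open. KRT5, a basal keratin of the urothelium, reached 1966 TPM in VM-CUB-1 with DMSO and 0.078 TPM at most in the DMSO libraries of the other lines. PAX8, a transcription factor of renal epithelium, stood at 107 TPM in Caki-1, against 1.03 TPM at most in the others. HOXB13, a prostate homeobox gene, had 0 counts in both DU-145 libraries, which allows up to 3 counts in each, or 0.16 CPM with DMSO. In other lines HOXB13 reached 3.26 TPM with DMSO and 5.98 TPM with LAK31, so no gene given here marks the DU-145 libraries as prostate. Of genes typical of other cell types, PTPRC of leukocytes, PECAM1 of endothelium, COL3A1 and LUM of fibroblasts and ALB of hepatocytes reached at most 0.06, 0.833, 0.336, 1.49 and 0.195 TPM in any library. Others in the list of such markers were higher, with CD68 of macrophages, PDGFRB of pericytes, and KDR and CDH5 of endothelium reaching 91.3, 31.04, 26.7 and 25.2 TPM in their highest library, and the median log2 fold change of the 14 list members measured in 2102EP was 1.13 (percentile 99.84 of matched lists), so the origin of these transcripts is left open.

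More genes were detected with LAK31 than with DMSO in each line. Genes with at least 10 reads numbered 15990 with DMSO and 17481 with LAK31 in 2102EP, 13631 and 14916 in VM-CUB-1, 14018 and 14852 in Caki-1, and 14540 and 15329 in DU-145. After all libraries were thinned to the smallest total, the gains were 1542, 1216, 903 and 746 genes in the same order, with SDs over repeated thinning of 12.7, 7.5, 11.2 and 7.0. The share of reads from the 13 protein-coding genes of the mitochondrial genome also differed within each line. It was 7.45% with DMSO and 18.1% with LAK31 in 2102EP, 3.97% and 6.38% in VM-CUB-1, 6.24% and 8.72% in Caki-1, and 6.3% and 8.39% in DU-145. No 95% Wilson interval reached further than 0.017 percentage points to either side of these shares.

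Across the 4 lines, the largest changes of genes named by rule were rises. DHRS2, a short-chain dehydrogenase known as a target of histone deacetylase (HDAC) inhibitors, had the largest estimate of the 10 genes taken as higher in all 4 lines, with a log2 fold change of 6.90 ± 0.39 (SE from the moderated F, n = 4 lines, adjusted p = 0.0081). The lines' own log2 fold changes of DHRS2 had a mean of 6.05 and an SD of 1.79. CYP4F12, named for its rise in VM-CUB-1 and called higher in 2 lines of the authors' deposited table, had a larger estimate across lines in edgeR (7.97 ± 1.05, adjusted p = 0.024). The mean of the lines' own log2 fold changes of CYP4F12 was lower, at 3.94 with an SD of 2.997. The calcium sensor HPCAL4 rose by 6.61 ± 0.97 (adjusted p = 0.024), the collagen gene COL5A3 by 6.18 ± 1.03 (adjusted p = 0.027), the vesicular glutamate transporter SLC17A7 by 6.09 ± 0.91 (adjusted p = 0.024) and the bone phosphatase PHOSPHO1 by 5.57 ± 0.81 (adjusted p = 0.024). RTBDN, ABAT, CACNA1G, ZDHHC11B and the neurotrophin receptor NGFR rose by 5.96, 5.5, 5.26, 4.99 and 4.73 (adjusted p between 0.024 and 0.046). Fitted values of genes with 0 counts in a DMSO library, as all of these but DHRS2, SLC17A7 and PHOSPHO1 had, depend on the prior count. RTBDN shares its locus with HOOK2, ZDHHC11B has a close paralog, and COL5A3, ABAT and CACNA1G overlap genes on the opposite strand, so their counts are less certain.

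The genes that fell most by the same rule had log2 fold changes between -2.58 and -3.81. TMEM35B fell by 3.81 ± 0.51 (adjusted p = 0.024), the nuclear receptor HNF4G by 3.55 ± 0.59 (adjusted p = 0.027), the collagen chaperone SERPINH1 by 2.89 ± 0.49 (adjusted p = 0.027), and CAP2, which binds actin, by 2.88 ± 0.30 (adjusted p = 0.022). RCBTB2, NMI, EFCAB2, the cytokine CLCF1, JADE2 and FAIM, an inhibitor of Fas-induced apoptosis, had changes of -3.09, -2.99, -2.77, -2.72, -2.65 and -2.58 (adjusted p between 0.023 and 0.037). TMEM35B shares its locus with annotated clone genes. All 20 genes went the same way in 4 of 4 lines, as the rule required.

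Of genes named in advance, CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339, GRCh38), rose by 1.44 ± 0.24 (adjusted p = 0.027). HEXIM1, an inhibitor of the elongation factor P-TEFb (chromosome 17, 45148502 to 45152101), rose by 0.85 ± 0.21 (adjusted p = 0.046). MYC (chromosome 8, 127735434 to 127741434) was not called across lines (-0.10 ± 0.39, adjusted p = 0.88). Its own log2 fold change was 1.49 in 2102EP, -0.88 in VM-CUB-1, -0.61 in Caki-1 and -0.28 in DU-145. DHRS2 lies on chromosome 14 from 23630115 to 23645639, HPCAL4 on chromosome 1 from 39678648 to 39691689, TMEM35B on chromosome 1 from 34981535 to 34985353 and CAP2 on chromosome 6 from 17393216 to 17557792.

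**Figure D1:**
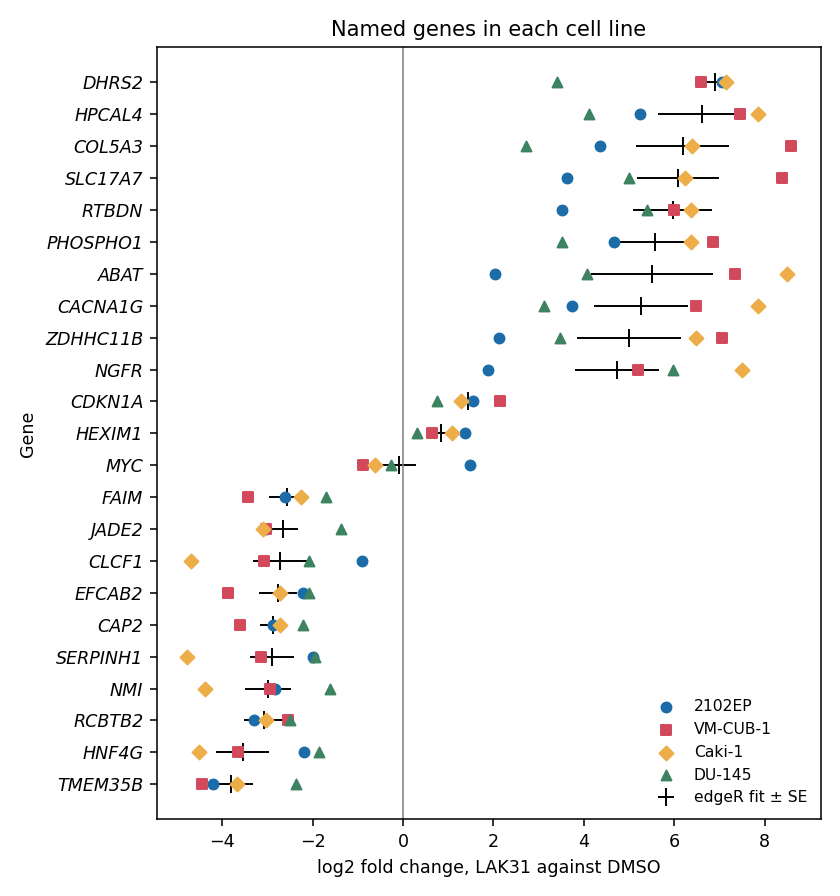
Log2 fold changes of LAK31 against DMSO (x axis) for the 20 genes named by rule and 3 named in advance (y axis), with 1 symbol per cell line and the edgeR estimate across lines as a black tick with its standard error. The genes at the top lie right of 0 and those at the bottom left of 0 in every line, while MYC lies at 1.49 in 2102EP and below 0 in the other lines.

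In total, 2120 of 17874 genes passed an adjusted p of 0.05 in edgeR, 1007 higher and 1113 lower with LAK31, and 5942 had an unadjusted p under 0.05. Of these, 971 of the higher and 1098 of the lower genes went the same way in all 4 lines. The count changed with the lines included, for it was 1192 without 2102EP, 206 without DU-145, 0 without VM-CUB-1 (4128 at an unadjusted p under 0.05) and 0 without Caki-1 (4171), so that no gene's adjusted call across lines held without VM-CUB-1 or without Caki-1. It was 0 with no block for cell line (1678 unadjusted) and 5091 with DESeq2. Of all genes tested, 41.4% had the same sign in all 4 lines, where 12.5% is the share of independent signs.

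Genes listed as induced by inhibitors of chromatin regulators, and histone genes, passed more often upward than downward. Of 24 genes listed as induced by HDAC inhibitors, 13 rose and 0 fell, and 18 rose and 2 fell adjusted over the list alone. Besides DHRS2 they included SYT11, a synaptotagmin, at 5.26 ± 0.35 (adjusted p = 0.012), and MAPT, the microtubule protein tau, at 3.19 ± 0.54 (adjusted p = 0.027). Of 14 genes listed as induced by inhibitors of BET bromodomain proteins, 10 rose and 0 fell (13 and 0 adjusted over the list alone), among them SERPINI1 at 3.36 ± 0.38 (adjusted p = 0.022), TXNIP, an inhibitor of thioredoxin, at 2.30 ± 0.31 (adjusted p = 0.024), and the histone gene HIST2H2BE at 2.22 ± 0.43 (adjusted p = 0.031). Of 30 replication-dependent histone genes, 13 rose and 0 fell (22 and 0 adjusted over the list alone), with HIST1H1E at 3.98 ± 0.60 (adjusted p = 0.025) and HIST1H2BG at 3.25 ± 0.41 (adjusted p = 0.023). These form a family of near-identical genes whose transcripts mostly lack a poly(A) tail, so single members are uncertain. The camera test gave adjusted p = 3.8e-13, 2.7e-09 and 1.8e-11 for these lists, and adjusted p = 0.57 with an estimated correlation for each. Without VM-CUB-1 or Caki-1, 0 members of any list passed over all genes, as above.

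Of 12 histone acetyltransferase genes, 5 fell and 1 rose (7 and 1 adjusted over the list alone), including KAT6B at -1.33 ± 0.20 (adjusted p = 0.026), CREBBP at -1.10 ± 0.15 (adjusted p = 0.024) and KAT7 at -1.04 ± 0.18 (adjusted p = 0.028). This list passed camera (adjusted p = 0.0098, and adjusted p = 0.57 with an estimated correlation), and it was the only one to pass fry, which asks whether members move 1 way on balance (adjusted p = 0.036). Of 18 HDAC and sirtuin genes, 3 rose and 1 fell, the same numbers as adjusted over the list alone, with SIRT2 at 1.48 ± 0.19 (adjusted p = 0.024) and HDAC7 at -2.20 ± 0.35 (adjusted p = 0.026). Of 11 variant histone genes, 3 rose and 2 fell (4 and 3 adjusted over the list alone), with H1FX at 1.08 ± 0.22 (adjusted p = 0.033) and H2AFY2, a macroH2A gene, at -2.04 ± 0.40 (adjusted p = 0.031). Of 15 genes of BET proteins and elongation, HEXIM1 rose and MEPCE, which caps the 7SK RNA, fell by 1.94 ± 0.35 (adjusted p = 0.029), while 1 rose and 2 fell adjusted over the list alone. Of 16 genes listed as repressed by BET inhibitors, 1 rose and 3 fell (1 and 6 adjusted over the list alone), the risen one being ID2, an inhibitor of differentiation, at 2.14 ± 0.51 (adjusted p = 0.043), and TFAP4 fell by 2.36 ± 0.40 (adjusted p = 0.027). Among 21 DNA methylation and Polycomb genes 1 rose and 1 fell (3 and 2 adjusted over the list alone). Without VM-CUB-1 or Caki-1 these member counts over all genes were 0. The last 5 lists did not pass camera (adjusted p = 0.62, 0.97, 0.68, 0.076 and 0.75).

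Of the MYC target, G1/S and G2/M genes that passed, all fell. Of 27 MYC target genes, 8 fell and 0 rose (19 and 0 adjusted over the list alone), with UTP20, of ribosomal RNA processing, at -1.65 ± 0.24 (adjusted p = 0.024), PPRC1 at -1.52 ± 0.32 (adjusted p = 0.034) and the cyclin-dependent kinase CDK4 at -1.23 ± 0.20 (adjusted p = 0.027). Of 28 G2/M genes, 8 fell and 0 rose (11 and 0 adjusted over the list alone), including the mitotic kinases AURKA at -1.40 ± 0.33 (adjusted p = 0.043) and PLK1 at -1.08 ± 0.19 (adjusted p = 0.029) and cyclin A2, CCNA2, at -1.17 ± 0.21 (adjusted p = 0.028). Of 26 G1/S genes, 5 fell and 0 rose (11 and 0 adjusted over the list alone), with thymidylate synthase, TYMS, at -2.37 ± 0.28 (adjusted p = 0.022) and the replication helicase subunit MCM5 at -1.22 ± 0.22 (adjusted p = 0.029). Camera gave adjusted p = 5.5e-08, 4.6e-06 and 1.4e-05, and adjusted p = 0.57 with an estimated correlation for each. The lists did not fall more than matched genes in each line, for in 2102EP the medians of MYC targets and G2/M genes, -0.11 and -0.19, lay at percentiles 95.86 and 81.44 of matched lists, G2/M genes in VM-CUB-1 lay at 16.95, and G1/S genes in Caki-1 at 37.6. Of 20 CDK inhibitors and growth arrest genes, 3 rose and 0 fell (7 and 1 adjusted over the list alone), namely CDKN1A, CDKN2D at 1.56 ± 0.30 (adjusted p = 0.031) and SESN3, a sestrin, at 3.17 ± 0.77 (adjusted p = 0.045). That list passed camera at adjusted p = 0.036 (adjusted p = 0.57 with an estimated correlation) but not without 2102EP (adjusted p = 0.13). Member counts over all genes were 0 without VM-CUB-1 or Caki-1.

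Genes of cell death went both ways. Of 10 anti-apoptotic genes, 3 fell and 1 rose, the same numbers as adjusted over the list alone. The caspase inhibitor XIAP and the caspase regulator CFLAR had changes of -0.94 ± 0.18 (adjusted p = 0.031) and -1.18 ± 0.19 (adjusted p = 0.026), while BIRC3 stood at 2.04 ± 0.45 (adjusted p = 0.037). The list passed camera at adjusted p = 0.039 (adjusted p = 0.57 with an estimated correlation), and not without 2102EP, Caki-1 or DU-145 (adjusted p = 0.083, 0.057 and 0.11). Of 23 pro-apoptotic genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone), with BMF, a BH3-only gene, at 3.72 ± 0.86 (adjusted p = 0.041) and BID, another, at -1.55 ± 0.23 (adjusted p = 0.024). Of 22 p53 targets, 2 rose and 1 fell (4 and 3 adjusted over the list alone). Neither of these lists passed camera (adjusted p = 0.92 and 0.68). Among 23 genes of homologous recombination and repair only the checkpoint kinase CHEK1 fell, by 0.82 ± 0.19 (adjusted p = 0.040), and 0 did adjusted over the list alone. That list passed camera at adjusted p = 0.018 (adjusted p = 0.57 with an estimated correlation), but not without VM-CUB-1 (adjusted p = 0.077). Over all genes, 0 of these members passed without VM-CUB-1 or Caki-1.

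Of the neuronal, lysosomal and mitochondrially encoded genes that passed, all rose. Of 28 neuronal genes, 7 rose and 0 fell (13 and 2 adjusted over the list alone), among them the neurexin NRXN2 at 6.06 ± 1.26 (adjusted p = 0.034), the dendritic microtubule protein MAP2 at 3.67 ± 0.67 (adjusted p = 0.029), and MAPT. Of 20 lysosome and autophagy genes, 4 rose and 0 fell (7 and 1 adjusted over the list alone), with WIPI1, of autophagosome formation, at 2.34 ± 0.46 (adjusted p = 0.031) and the sialidase NEU1 at 2.14 ± 0.40 (adjusted p = 0.029). Of the 13 mitochondrially encoded genes, MT-CYB passed at 0.79 ± 0.20 (adjusted p = 0.046), and all 13 rose adjusted over the list alone, beside the larger mitochondrial share of reads with LAK31 in each line. Camera gave adjusted p = 0.00013, 0.014 and 0.00033, and adjusted p = 0.57 with an estimated correlation for each, while fry gave adjusted p = 0.076, 0.099 and 0.11. Here too, member counts over all genes were 0 without VM-CUB-1 or Caki-1.

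Of 30 ribosomal protein genes, 4 fell and 0 rose (10 and 0 adjusted over the list alone), with RPL10 at -0.72 ± 0.15 (adjusted p = 0.034) and RPL6 at -0.70 ± 0.14 (adjusted p = 0.032). Among 23 housekeeping genes, PPIA, or cyclophilin A, and HPRT1 fell by 0.70 ± 0.17 and 0.75 ± 0.18 (adjusted p = 0.045 for both), and 0 passed adjusted over the list alone. Camera gave adjusted p = 9.4e-06 for ribosomal proteins and 0.023 for housekeeping genes, which did not pass without 2102EP (adjusted p = 0.23), and each had adjusted p = 0.57 with an estimated correlation. Against lists matched on expression, the ribosomal protein medians lay at percentiles 40.92 in 2102EP, 48.22 in VM-CUB-1, 7.68 in Caki-1 and 2.42 in DU-145, and those of housekeeping genes at 3.98, 76.98, 56.02 and 21.47, so ribosomal protein genes in 2102EP and VM-CUB-1 fell about as much as matched genes. Of 21 genes of the unfolded protein response, 4 fell and 0 rose (6 and 1 adjusted over the list alone), including XBP1 at -1.48 ± 0.30 (adjusted p = 0.033), TRIB3 at -1.46 ± 0.34 (adjusted p = 0.042) and the cystine transporter SLC7A11 at -1.45 ± 0.29 (adjusted p = 0.033), with camera at adjusted p = 0.10. Of 10 drug transporters, the efflux pump ABCB1 rose by 3.68 ± 0.61 (adjusted p = 0.027), and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.74). The calls over all genes in these lists were lost without VM-CUB-1 or Caki-1.

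The other lists did not pass camera. Of 20 NF-kappaB genes 1 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.57), of 24 immediate early genes 2 rose and 0 fell (1 and 0 adjusted over the list alone, 0.14), and of 17 heat shock genes 2 rose and 3 fell (3 and 6 adjusted over the list alone, 0.60). Interferon genes had 1 risen and 1 fallen of 23, the same adjusted over the list alone (0.70), antigen presentation 0 and 1 of 19 (5 and 2 adjusted over the list alone, 0.27), and hypoxia 2 and 1 of 20 (3 and 2 adjusted over the list alone, 0.76). Single members rose, and 0 fell, among 24 epithelial, 20 mesenchymal, 14 urothelial and 14 renal genes (0, 1, 3 and 1 adjusted over the list alone, 0.50, 0.12, 0.094 and 0.099). In the lists of 28 pluripotency, 14 differentiation, 10 germ cell, 9 prostate, 21 cholesterol, 8 metallothionein and 10 other cell type genes, 0 members passed over all genes or adjusted over the list alone (0.45, 0.19, 0.19, 0.38, 0.88, 0.14 and 0.056). Camera's direction was down, against a median and mean above 0, for variant histone, pro-apoptotic, heat shock and cholesterol genes. It was down with a median below and a mean above 0 for Polycomb, NF-kappaB, hypoxia and transporter genes. With a trend in GC content removed, the median of the variant histone genes was below 0. Of the 41 lists, 7 passed upward and 8 downward with the preset correlation and 0 with an estimated one, and fry's test for change in either direction passed 38.

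**Figure D2:**
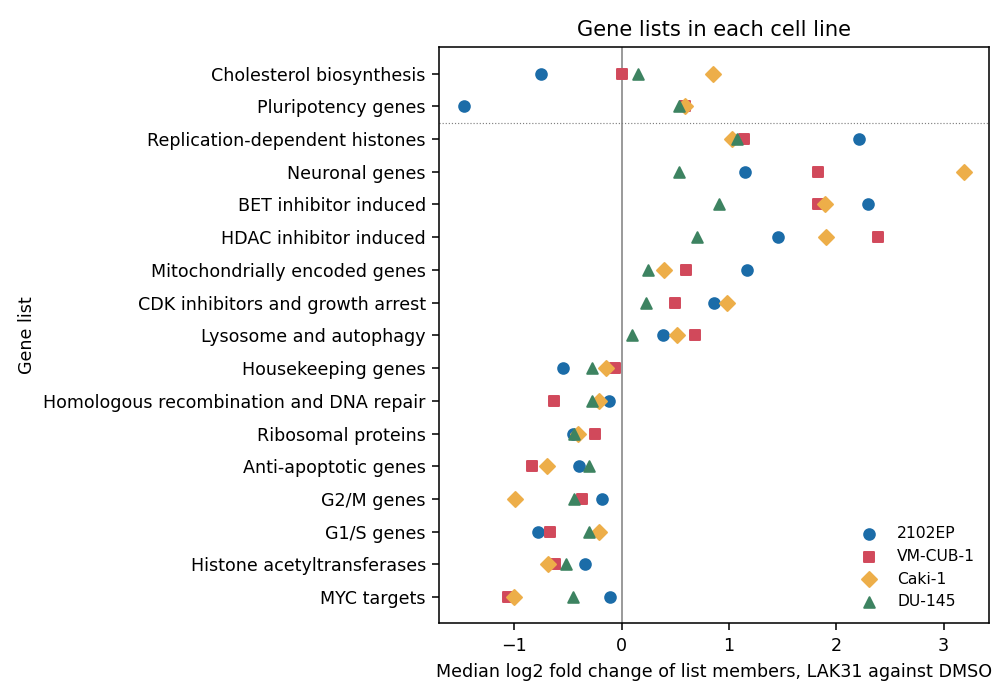
Median log2 fold change of LAK31 against DMSO over the measured members of each list (x axis) for the 15 lists that passed camera with the preset correlation and, above the dotted line, 2 lists that did not (y axis), with 1 symbol per cell line. The pluripotency median lies at -1.46 in 2102EP and between 0.54 and 0.59 in the other lines, and that of replication-dependent histones at 2.21 in 2102EP and between 1.03 and 1.14 in the others. In the carcinoma lines, the pluripotency medians lie between percentiles 83.51 and 84.96 of matched lists.

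Within single lines, the authors' deposited table called 4014 genes higher and 3870 lower with LAK31 in 2102EP. DHRS2, at 137-fold (95% counting interval 110 to 174), was among the largest rises called in the authors' deposited table, next to FRG2, at least 83.8-fold higher, and the amino acid transporter SLC36A2, at 152-fold (51.8 to 742). HPCAL4 was 113-fold higher (19.9 to 4514) on 1 count with DMSO, and the readthrough gene DYX1C1-CCPG1 at least 59.6-fold. Among genes called lower in the authors' deposited table, GAD2, a glutamate decarboxylase, was 40.9-fold lower (22.0 to 86.0), OR52A1 29.7-fold (7.86 to 251), TMEM35B 24.6-fold (11.1 to 68.3), CCDC129 19.1-fold (14.3 to 25.9) and FOXD1-AS1 16.1-fold (4.11 to 139). Of 28 pluripotency genes, 22 were lower in the authors' deposited table and 0 higher, with a median log2 fold change of -1.46 (-1.47 with members at 0 counts set to their bound), the lowest of 10000 matched lists to the precision kept (percentile 0.00). NODAL was 9.47-fold lower (7.37 to 12.3), GDF3 7.49-fold (7.02 to 7.99), NANOG 3.17-fold (3.04 to 3.30), LIN28A 3.03-fold (2.97 to 3.09) and POU5F1 1.84-fold (1.80 to 1.88). Of 40 measured replication-dependent histone genes, 27 were higher in the authors' deposited table, at a median of 2.21 (3.04 at the bound, percentile 100). Of 21 cholesterol synthesis genes, 13 were lower there, with CYP51A1 3.14-fold lower (2.87 to 3.44). The mitochondrially encoded genes, 13 of 13 called higher in the authors' deposited table, had a median of 1.17.

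In VM-CUB-1, 3958 genes were higher and 3855 lower with LAK31 in the authors' deposited table. COL5A3, the cytochrome CYP4F12, the neural adhesion gene L1CAM, the chemokine receptor CXCR5 and NRXN2 had 0 counts with DMSO and were at least 226-fold, 151-fold, 122-fold, 101-fold and 96.6-fold higher. On the lower side of the authors' deposited table, SENP3-EIF4A1, TMEM265 and TMED7-TICAM2 had 0 counts with LAK31 and were at least 38.5-fold, 33.1-fold and 24.7-fold lower. The first and last of these are readthrough genes, whose reads can be assigned to either partner. SIGLEC15, a sialic acid receptor, and TMEM88 were each 40.4-fold lower (10.8 to 340, and 6.81 to 1637). Of 27 MYC targets, 21 were lower and 1 higher in the authors' deposited table, at a median of -1.06 (percentile 0.00), with PPRC1 5.58-fold lower (5.15 to 6.05). Among 19 NF-kappaB genes, 12 were lower and 2 higher there, at a median of -1.19 (-0.97 at the bound, percentile 0.00), and NFKB1 itself was 8.33-fold lower (7.44 to 9.33). Of 22 p53 targets, 12 were higher and 4 lower in the authors' deposited table, with TP53INP1 43.9-fold (22.9 to 96.7) and GDF15 12.2-fold higher (9.51 to 15.9).

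In Caki-1, 3925 genes were higher and 3692 lower in the authors' deposited table. ABAT, which degrades GABA, HPCAL4, the T-type calcium channel CACNA1G, the peptidylarginine deiminase PADI2 and HID1 had 0 counts with DMSO and were at least 236-fold, 153-fold, 152-fold, 139-fold and 137-fold higher. EVI2A, which lies inside NF1 on the opposite strand, was 165-fold lower (64.1 to 607), and the interleukin 7 receptor IL7R was 39.0-fold lower (30.8 to 50.2), both called in the authors' deposited table. TICAM2 was at least 85.0-fold lower, MARVELD2, of tricellular junctions, 55.8-fold (15.1 to 467) and GIMAP2 42.5-fold (7.23 to 1716). The AP-1 gene FOSL1 was 27.6-fold lower (24.7 to 30.9) and PAX8 was 3.43-fold lower (3.23 to 3.65), both called in the authors' deposited table. Of 24 immediate early genes, 19 were higher and 4 lower there, at a median of 1.46 (percentile 100), with EGR2 62.4-fold higher (21 to 305). Of 28 G2/M genes, 22 were lower and 0 higher in the authors' deposited table, at a median of -0.99 (percentile 0.00), with AURKA 5.67-fold (5.30 to 6.07) and CCNB1 3.55-fold lower (3.37 to 3.74). Of 21 cholesterol synthesis genes, 14 were higher and 0 lower there, at a median of 0.85, with INSIG1 5.62-fold higher (5.19 to 6.08). Neuronal genes had 16 higher and 2 lower of 27 in the authors' deposited table, at a median of 3.19 (3.65 at the bound), with the synuclein SNCB at least 101-fold higher.

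In DU-145, 2369 genes were higher and 2278 lower in the authors' deposited table. RTBDN was 122-fold higher (21.6 to 4869) on 1 count with DMSO, and NGFR 103-fold (34.9 to 501) on 3. The protease gene PRSS35, the sodium pump subunit ATP1B2 and the tubulin ligase gene TTLL6 were 62.5-fold, 61.6-fold and 61.6-fold higher, each on 1 count with DMSO and with a lower interval bound no higher than 10.9. Of genes lower in the authors' deposited table, TNFRSF6B, a decoy receptor for Fas ligand that overlaps a readthrough gene, fell from 290 to 0 counts and was at least 110-fold lower. SPDEF, an ETS factor of prostate epithelium, was 15.9-fold lower (4.01 to 138), GTF2IRD2B, which has near-identical copies, 14-fold (6.49 to 35.7), C1QTNF3-AMACR, a readthrough gene, 11.1-fold (4.46 to 35.8) and ADIRF-AS1 10.9-fold (7.82 to 15.6). Of 21 genes of the unfolded protein response, 9 were lower and 1 higher in the authors' deposited table, at a median of -0.50 (percentile 0.08), with SLC7A11 2.22-fold (2.05 to 2.40) and DDIT4 2.11-fold lower (1.91 to 2.32). Of 12 acetyltransferase genes, 6 were lower and 0 higher there, at a median of -0.52 (percentile 0.42), with CREBBP 2.33-fold lower (2.15 to 2.54). Beside the smaller number of calls, the log2 fold changes of DU-145 were spread less, with an SD over 17874 genes of 0.85, against 1.06 to 1.39 in the other lines, and of 0.443 over genes above 100 CPM, against 0.747 to 0.871. More than 2-fold changes were seen for 17.5% of these genes in DU-145 and for 27.3% to 35.0% in the others. With 1 library per line and treatment, this difference between lines has no replicate check.

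These counts rest on deposited p-values that, for genes with more than 500 counts, follow a fixed coefficient of variation of 5.59%. With the same 5.59%, genes and thresholds, an edgeR exact test, which is another tool with its own scaling, called 8462 genes in 2102EP, 8460 in VM-CUB-1, 8166 in Caki-1 and 4994 in DU-145. In that test, 10% gave 8030, 8192, 7937 and 4539 calls, 20% gave 3460, 4656, 4366 and 1188, and 40% gave 280, 1051, 866 and 49. Across lines, edgeR estimated a common coefficient of variation of 34.9%, which includes the difference of responses between lines.

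**Figure D3:**
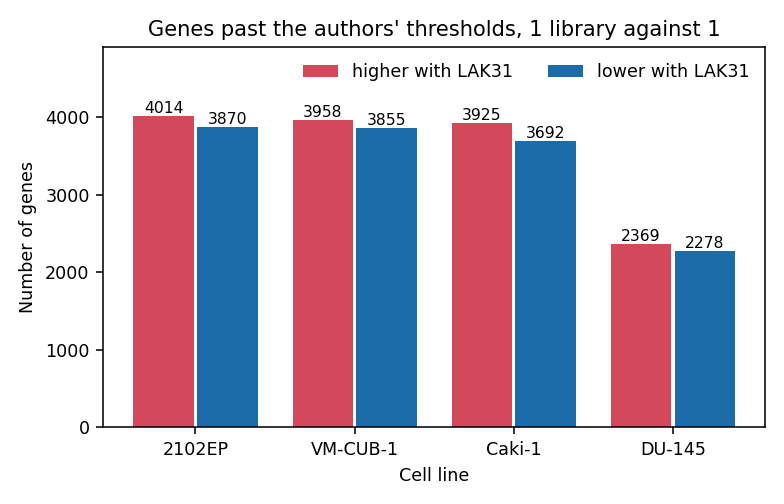
Numbers of genes (y axis) past the authors' FDR of 0.05 and fold change of 1.5 in each cell line (x axis), higher (red) and lower (blue) with LAK31, from the authors' deposited table of 1 library against 1. The bars stand at 4014 and 3870 in 2102EP, 3958 and 3855 in VM-CUB-1, 3925 and 3692 in Caki-1, and 2369 and 2278 in DU-145.

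The differences between LAK31 and DMSO libraries were partly shared by the lines. Among 17560 genes tested in all 4 comparisons of the authors' deposited table, 668 were higher and 679 lower in every line, where independent lists of these sizes would share 19.2 and 17.7. Such numbers for independent lists take every gene as equally likely to be called and were not matched on expression. Leaving out a line cannot lower the total shared, by construction. From 1347 it went to 2231 without 2102EP, 1572 without VM-CUB-1, 1609 without Caki-1 and 2448 without DU-145, the line with the fewest calls. Independent lists would share 193.2, 174.0, 178.7 and 294.1 in the same order. Of the genes shared by all 4 lines, 515 of the higher and 619 of the lower ones also passed the edgeR test across lines. Genes called in both lines of a pair in the authors' deposited table went the same way in 94.7% of cases for VM-CUB-1 and Caki-1, 93.9% for Caki-1 and DU-145 and 93.6% for VM-CUB-1 and DU-145. For 2102EP the shares were 87.0% with VM-CUB-1, 86.1% with Caki-1 and 84.9% with DU-145. Over genes, which are not independent replicates, log2 fold changes correlated at Pearson's r = 0.61 (Spearman's rho 0.63) for VM-CUB-1 and Caki-1 and at 0.37 (0.37) for 2102EP and DU-145, the ends of the range over the 6 pairs. In the authors' deposited table, 1177 genes were called higher in some line and lower in another. The difference between 2102EP and the carcinoma lines could not be tested as an interaction.

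The direction of change varied with expression level. With genes split into 10 equal groups by mean CPM, of the 1787 genes in the highest group 60 rose and 313 fell across lines, and their median log2 fold change was -0.36 in 2102EP, -0.24 in VM-CUB-1, -0.22 in Caki-1 and -0.16 in DU-145. In the third group from the lowest, 125 rose and 6 fell, with medians of 0.42, 0.53, 0.38 and 0.25 in the same lines. The trend did not run on to the lowest group in the carcinoma lines. There, 29 rose and 0 fell, with medians of 0.449, 0.139, 0.006 and 0.0 in the same order of lines. By gene type, 960 of 15412 protein-coding genes rose and 1089 fell, while 14 of 866 antisense genes rose and 2 fell. Genes that went from at most 3 counts to at least 10 with LAK31 numbered 841, 908, 788 and 415 in the same order of lines, and the reverse held for 106, 127, 152 and 87. ABCD2, CFAP99, CREB3L3 and GMNC, chosen after their values were seen, had at most 3 counts in all DMSO libraries and at least 10 in all LAK31 libraries, and 0 genes showed the reverse. CREB3L3, a liver transcription factor, had 161, 68, 177 and 10 counts with LAK31.

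**Figure D4:**
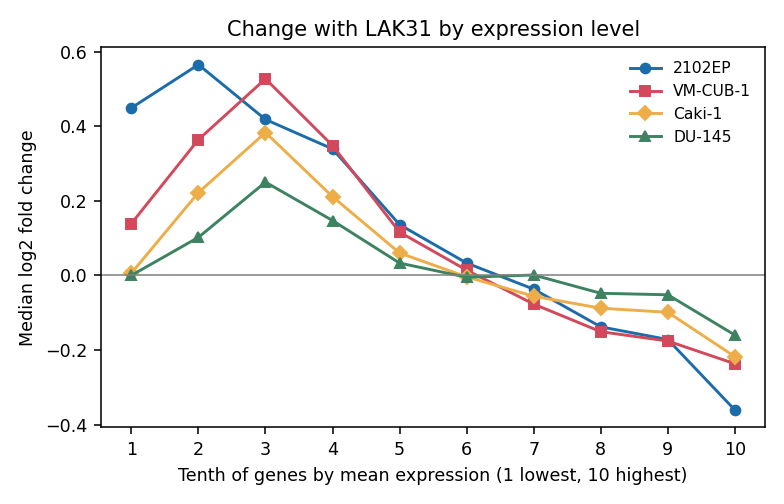
Median log2 fold change of LAK31 against DMSO (y axis) over genes split into 10 equal groups by mean CPM over all libraries (x axis, 1 lowest), with 1 line per cell line. Medians lie between -0.16 and -0.36 in the highest group, between 0.25 and 0.53 in the third and between 0.0 and 0.45 in the lowest.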

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

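Of the tests here, those on other splits of the libraries, leaving out mitochondrially encoded genes, thinned depth, the room left by abundant transcripts and swapped labels, and the correction for GC content, were chosen after the results they bear on were seen. The values listed below were picked because 1 line lay far from the other 3, or because 2102EP moved opposite to all 3 carcinoma lines. With 1 library per line and treatment, none of these differences between lines was tested. The first criterion picks about 1 in 20 sets by chance, and it picked 8 of 161 where 8.1 would be picked by chance alone.

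In 2102EP, the log2 fold change of the efflux transporter ABCC3 was 2.25, against -1.99 to -1.36 in the other lines, and met both criteria. That of the nucleoside transporter SLC29A1 was -1.17 in 2102EP, against -0.45 to -0.41. In DU-145, DHRS2 stood at 3.4, against 6.6 to 7.15, ID2 at 0.04, against 2.59 to 2.95, and JADE2 at -1.37, against -3.1 to -3.02. In Caki-1, SLC7A11 stood at -2.59, against -1.15 to -1.02. Replication-dependent histone genes had a median of 2.21 in 2102EP, against 1.03 to 1.14. Pluripotency genes had a median of -1.46 in 2102EP, against 0.54 to 0.59, and met both criteria, although only 18 to 20 of the 28 had reads in the other lines. MYC stood at 1.49 in 2102EP, against -0.88 to -0.28, PODXL at -0.71, against 0.66 to 2.65, and SOX2 at -0.68, against 1.7 to 4.19, on 0 counts with DMSO in Caki-1 and DU-145. Cholesterol synthesis genes had a median of -0.75 in 2102EP, against 0.002 in VM-CUB-1, 0.15 in DU-145 and 0.85 in Caki-1. In VM-CUB-1, 2 of them were called higher and 3 lower, so that line met the second criterion by the sign of its median only.

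The first pattern weighed is the change of 2120 genes across the lines. Of the 8 splits of the libraries that part all 4 pairs, 1 gave as many genes, the real one with 2120, and the highest count of the others was 0, but 8 splits are too few for a share under 0.05. Another 24 splits part only 2 pairs and put both libraries of the other lines into 1 group, so they are not comparable. With the trend on GC content removed in each line, 2078 of the 2120 genes were still called, which argues against that trend as the whole cause. With the mitochondrially encoded genes left out of the counts, 2011 of the 2120 were still called. TMM scaling already takes out a shift shared by most genes in the main fit, so this count cannot decide on displacement by mitochondrial reads. An effect of LAK31 remains a hypothesis, and 16 h at the EC50 leaves open how much comes from dying or arrested cells, which was not tested.

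The next pattern is the larger number of genes with at least 10 reads in the LAK31 library of each line. Thinned to 1 total, the smallest gain was still 746 genes, in DU-145, which argues against deeper LAK31 libraries. Mixing of RNA between these lines, read from genes specific to each source line, could supply the rise of at most 0.59% of the gained genes over the 12 pairs of lines. The genes read were 56 for 2102EP as the source, 11 for VM-CUB-1, 9 for Caki-1 and 2 for DU-145. The 0.59%, for DU-145 as the source in 2102EP, rests on these 2 genes, so bounds for the carcinoma lines as sources are uncertain. With the genes that were among the 100 most abundant in either library of a line left out and the rest thinned to 1 total, the smallest gain was 743 genes, again in DU-145, with an SD over repeated thinning of 9.3, which argues against room left by abundant transcripts. The 100 most abundant genes took a smaller share with LAK31 in DU-145 alone, by 0.15 percentage points. These tables leave open a wider activation of silent genes by LAK31, and a difference in DNA carried into the libraries or in unspliced RNA, neither of which can be read from gene counts.

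The last pattern is that 2102EP moved against the carcinoma lines in MYC and other genes. Of 1437 genes called in 1 direction in all 3 carcinoma lines and also called in 2102EP, 93.7% went the same way there, which argues against swapped LAK31 and DMSO labels in 2102EP. The other 90, or 6.3%, went the opposite way, where the same count for each carcinoma line against the remaining 3 gave between 0.6% and 1.7%. Open explanations are the germ cell origin of the line, its other culture medium, which the labels give as DMEM and as an RPMI medium for the others, and a different dose at its EC50, all of which coincide in this design and were not tested.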

How the results depend on the processing

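Planned before the data were examined were all settings here except leaving out mitochondrially encoded genes, the GC correction, the assumed coefficients of variation and the list tests without each line. With no cell line block, edgeR called 0 genes (1678 unadjusted). Leaving out a line gave between 0 and 1192 genes. Each such fit had fewer residual degrees of freedom than the main fit. Their number was the same whichever line was left out, so it does not account for the spread between these counts, whose cause was not tested. DESeq2 gave 5091 and an adjusted p under 0.1 gave 4426. Between 2057 and 2625 genes were called with other size factors (2093), no expression filter (2553), limma (2625), the mitochondrial genes left out (2057) or the GC trend removed (2555). In the authors' deposited table, an absolute fold change of at least 2, under which fewer genes qualify by construction, gave 4731 calls in 2102EP, 5141 in VM-CUB-1, 4927 in Caki-1 and 2332 in DU-145. The authors' Bonferroni p-values left 5024, 5578, 5510 and 2749 in the same order, and their FDR with no fold threshold gave 10364, 10010, 9964 and 7328. In an edgeR exact test per line on the same genes and thresholds, a change of tool and scaling, assumed coefficients of variation of 5.59%, 10%, 20% and 40% gave 8462, 8030, 3460 and 280 in 2102EP, 8460, 8192, 4656 and 1051 in VM-CUB-1, 8166, 7937, 4366 and 866 in Caki-1, and 4994, 4539, 1188 and 49 in DU-145, falling by construction. The overlap of the deposited calls over all lines was 477 at a fold of at least 2 and between 1572 and 2448 without 1 line. With an estimated correlation, 0 of the 15 lists passed.

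Values that turned in direction were not called in either setting, and the cause was not tested. With no block, CCND2, PODXL and SOX2 stood at -0.74, -0.41 and -0.52, and DESeq2 gave LIN28A 0.041. Leaving out a line moved MYC between -0.56 and 0.19, with 0.10 without Caki-1, PAX8 between -0.91 and 0.43, and POU5F1 between -0.52 and 0.20. Of the 84 named genes called across lines, 84 were still called with DESeq2 and with the GC trend removed, 83 with other size factors, 82 with no filter, 81 with limma, 81 without mitochondrial genes, 58 without 2102EP, 16 without DU-145 and 0 without VM-CUB-1, without Caki-1 or with no block. Over all named genes and settings, 1017 values kept direction and side of the threshold, 359 lost the call, 42 gained it and 8 turned. Per line, 205 values of named genes were kept and 35 lost the call. With at least 1 TPM required, or centred on all genes, 80 list medians averaged over lines were kept and 1 moved. These averages hide turns in single lines when 1 TPM was required. Among them, renal genes in Caki-1 went from 0.167 to -0.564, prostate genes in VM-CUB-1 from 1.111 to -0.641 and mesenchymal genes in DU-145 from 0.467 to -0.17. Of the 41 medians of edgeR estimates, limma made 17 smaller by over 1.5 times, the GC correction 5, DESeq2 3, other size factors 1 and leaving out mitochondrial genes 1 of 40. The GC correction made 3 larger by over 1.5 times and DESeq2 1, and only variant histones turned, with the GC correction (0.156 to -0.124). Pro-apoptotic genes went from 0.265 to 0.047 and HDAC and sirtuin genes from 0.322 to 0.154 with that correction. Replication-dependent histones went from 2.03 to 0.937 with limma, neuronal genes from 1.702 to 0.925, other cell type markers from 1.384 to 0.291, and pluripotency genes from -0.706 to -0.305 (-0.149 with DESeq2). Settings for files that hold only normalized values were not run, since counts were deposited. Depth limits genes near 0 counts, where folds are bounds.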

Other observations

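Gene Ontology terms were tested for enrichment among the genes called across lines after the data had been seen, over 2720 tests with 11579 annotated genes as background. A hypergeometric test across genes, which are not independent, gave 12 terms for the risen and 42 for the fallen genes at an adjusted p of 0.05. This test does not allow for expression level, and highly expressed genes fell more often. Against draws matched on expression, the fallen terms translation, viral transcription, SRP-dependent protein targeting and nonsense-mediated decay had unadjusted p = 0.05, 0.05, 0.08 and 0.1. Genes of cilia were enriched among those that rose, though most of them did not pass. Of 30 genes of cilium movement, 10 rose and 1 fell, where 1.88 risen ones would be drawn by chance (adjusted p = 0.0019), and their median log2 fold change was 1.16 in 2102EP, 1.87 in VM-CUB-1, 1.47 in Caki-1 and 0.96 in DU-145. They included the dynein gene DNAI1 at 3.70 ± 0.78, the dynein assembly factors ZMYND10 at 3.50 ± 0.87 and DNAAF1 at 3.37 ± 0.74, and the radial spoke gene RSPH4A at 3.21 ± 0.54 (SE, n = 4 lines, edgeR adjusted p between 0.027 and 0.047). Of 153 genes of cilium assembly, 24 rose and 7 fell, where 9.58 were drawn by chance. GMNC, a regulator of multiciliated cell fate, and CFAP99, of cilia, were also among the 4 genes with at least 10 counts in all LAK31 libraries and at most 3 in all DMSO libraries. Of 18 genes of semaphorin-plexin signalling, which guides axons, 6 rose and 1 fell, with SEMA6C at 2.52 ± 0.59 (adjusted p = 0.042) and PLXNA3 at 1.66 ± 0.30 (adjusted p = 0.029). Draws matched on expression gave 2.14 risen genes for cilium movement and 10.5 for cilium assembly.

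Genes of chromatin remodelling and RNA processing were enriched among those that fell, though most RNA processing genes did not pass. Of 12 genes of nucleosome disassembly, 8 fell and 0 rose, where 0.87 would be drawn by chance (adjusted p = 0.00019) and 1.6 with matched expression. ARID1A, ARID2, SMARCD1 and PBRM1, subunits of SWI/SNF remodelling complexes, stood at -1.41 ± 0.25, -1.24 ± 0.24, -0.94 ± 0.16 and -0.80 ± 0.16 (adjusted p between 0.027 and 0.033). Of 225 mRNA splicing genes, 43 fell and 1 rose, where 16.3 were drawn by chance and 29.1 with matched expression, among them U2AF2, which binds ahead of the 3' splice site, at -1.53 ± 0.14 (adjusted p = 0.021) and RBMX at -1.63 ± 0.23 (adjusted p = 0.024). Of 118 translational initiation genes, 31 fell and 0 rose, where 8.56 and, with matched expression, 19.8 were drawn. The matched draws gave unadjusted p = 0.0001 for nucleosome disassembly and 0.004 for both splicing and initiation. Of 14 genes of stress granule assembly, 7 fell and 0 rose, with DDX6 at -1.21 ± 0.22 (adjusted p = 0.029). Against lists matched on expression, the median of splicing genes in DU-145 lay at percentile 12.7, those of initiation genes in 2102EP and VM-CUB-1 at 7.49 and 9.36, and that of stress granule genes in DU-145 at 21.58. No adjusted call of a single gene here held without VM-CUB-1 or without Caki-1.

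A hypothesis set down before its test was that LAK31 may lower the genes that set a line apart more than other genes of the same expression. Genes with at least 8-fold higher mean expression in 1 line than in each other line had a median log2 fold change of -0.27 in 2102EP (428 genes), -0.41 in VM-CUB-1 (104), -1.18 in Caki-1 (79) and -0.38 in DU-145 (42). Expression-matched lists of other genes had medians of -0.10, -0.16, -0.10 and -0.09. The highest percentile of the 4 among 10000 matched lists was 0.46, in VM-CUB-1, so for genes set apart by expression the values went with the hypothesis in 4 of 4 lines. Over all measured members, the lists of tissue genes did not fall in the carcinoma lines. Their medians were 1.02 for urothelial genes in VM-CUB-1 (percentile 99.56), 0.17 for renal genes in Caki-1 (58.72) and 0.55 for prostate genes in DU-145 (91.84). With at least 1 TPM required, the medians were 1.06 over 13 members, -0.56 over 9 and 0.52 over 4 in the same order. The renal genes expressed in Caki-1 thus fell at the median. The pluripotency genes fell in 2102EP, with a median of -1.46 (percentile 0.0). The lists describe these 8 libraries, and whether the treatment acts on identity genes as such, or on genes with strong enhancers or short-lived transcripts, was not tested.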
